A study of Penaeus japonicus with 32 samples.

How the data were processed

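Hemocytes, the circulating blood cells of the hemolymph, were measured in kuruma shrimp (Penaeus japonicus). Per the labels, shrimp received 100 µl by intramuscular injection of phosphate buffered saline (PBS), of long double-stranded RNA encoding green fluorescent protein (dsGFP) or of small interfering RNA encoding it (siGFP), each RNA at 3 µg per g of body weight. Hemolymph was drawn 24 h or 48 h later from 4 shrimp per treatment and time, and from 8 untreated shrimp at 0 h. Green fluorescent protein is foreign to shrimp, so neither RNA was chosen against a shrimp gene. The series' design text says that different shrimp were used in each group, so each array was taken as 1 animal. For each sample 200 ng of total RNA was labelled with the dye Cy3 and hybridised to a 1-colour Agilent array.

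The deposited scanner files hold intensity values made with Agilent Feature Extraction version 10.7.3.1, per the file headers and the submitters' processing notes. The processed signal in them is a background-subtracted intensity on a linear scale, not yet scaled between arrays, per the file headers. The authors also deposited a value table in log2 units. Set against the scanner signals, each value in it was, apart from a constant per array, the log2 processed signal minus its mean over 7 untreated arrays. Untreated replicate 1 was outside that mean. With this reading the deposited log2 values and those computed here differed, apart from a constant per array, by at most 1.68e-06 at the 99th percentile of every array, against 0.826 with all 8 untreated arrays as baseline. The medians of its columns ran from -0.18 to 1.70. The log2 scale, the direction and the baseline arrays were settled by this match, while the constant taken from each array was not.

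Each array holds 13875 probes, with 1 spot each, beside 459 positive and 77 negative control spots that were left out. No probe was saturated. Main values were log2 processed signals minus each array's 75th percentile over the probes that are not controls, with spots marked as outliers by the scanner software left out (0 to 10 per array). A probe was tested where it was well above background on at least 4 of the 32 arrays, which kept 11385 probes. All 32 arrays of the 7 groups entered 1 limma model (limma 3.58.1 in R 4.3.3) with a mean per group and moderated variances with trend and robust fitting (statmod 1.5.0). P-values are two-sided and were adjusted by the Benjamini-Hochberg method within each of the 13 comparisons, with a threshold of 0.05. The number of arrays limits the precision.

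Each slide held 1 treatment: slide 1 the PBS arrays, slide 2 dsGFP, slide 3 siGFP and slide 4 the untreated arrays. Each slide was scanned in 1 session, so slide, scan and treatment cannot be told apart in any comparison between treatments. Time lay within a slide, with 24 h in row 1 and 48 h in row 2. Untreated arrays filled both rows. The interaction of treatment with time is free of a constant shift of a slide.

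Probe names in the files are GenBank entries (465 probes), numbers with the prefix wsv (526), clone sequences (39) and assembled transcripts given by a locus number (12845 probes of 8374 loci, 3333 of them from 1 locus, Locus_3). The files used here pair none of these with gene names, and 0 of the probes matched an accession in the reference table provided. All 18 gene lists and the cell type markers fixed before the data were examined work by gene name. Each list matched 0 probes, so no list test was possible, and the virus list did not match the wsv prefix. Probes are therefore given by identifier, at most 2 higher and 2 lower per comparison. They are those with the largest fold changes past the threshold whose groups do not overlap and of which at least 1 group is well above background on all its arrays. Names other than a locus number went first, a preference set after the files were examined, and a locus probe was named, with its probe number, only where no other was left. Where nothing passed, the 2 of smallest p each way are given as values, taken only from probes without a locus number and well above background on all arrays of at least 1 group. Where the dimmer group was not well above background on any array, the fold is a lower bound, written as at least N-fold: the bright group's mean against the mean over the dim group's arrays of the higher of the probe's signal and the lowest signal well above background.

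On simulated data with 200 changed probes among 11385, the model for dsGFP against PBS at 24 h recovered 5.88% of changes of 1 on the log2 scale, 66.7% of changes of 2 and 77.3% of changes of 3, with 4 false calls. For PBS at 24 h against untreated these shares were 17.6%, 83.3% and 89.4%, with 7 false calls, and for the dsGFP by time interaction 1.47%, 37.9% and 65.2%, with 2 false calls. The simulated noise was normal and independent for each probe and array, with 1 spread per probe. It held no weak arrays, slide shifts or correlation between probes, so the false calls are not the error rate of the real arrays.

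Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter on dim probes, a filter requiring signal well above background on all arrays compared, a model of only the groups compared, the deposited value table, the replicate number as a block, a 2-fold minimum, variances without trend and robust fitting, the array row as a covariate, untreated arrays in place of PBS, and each array left out in turn. Normexp used the median spot signal, since the mean signal was not among the columns of the scanner files. Fits without the 2 weakest arrays and without untreated replicate 2 were chosen after seeing the data.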

Results

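The 32 arrays measured the hemocyte RNA of 4 shrimp in each of 6 injected groups and of 8 untreated shrimp. The number of probes well above background ran from 5369 to 10999 per array, with a median of 9898 of 13875, and the 75th percentile of the signal from 76.4 to 449 scanner units. Some arrays stood apart. Those of dsGFP 24 h replicate 4 and untreated replicate 1 had 5369 and 6538 probes well above background and 75th percentiles of 76.4 and 98.3. They are called the weak arrays below, and counts without them, chosen after seeing the data, stand beside the main counts. Untreated replicate 2 held 108 probes over 16-fold brighter there than on any other array. Correlations between arrays across probes had a median of 0.95 within groups and 0.94 between groups. The highest was 0.98, and the lowest 0.68 within and 0.66 between groups.

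**Figure D1:**
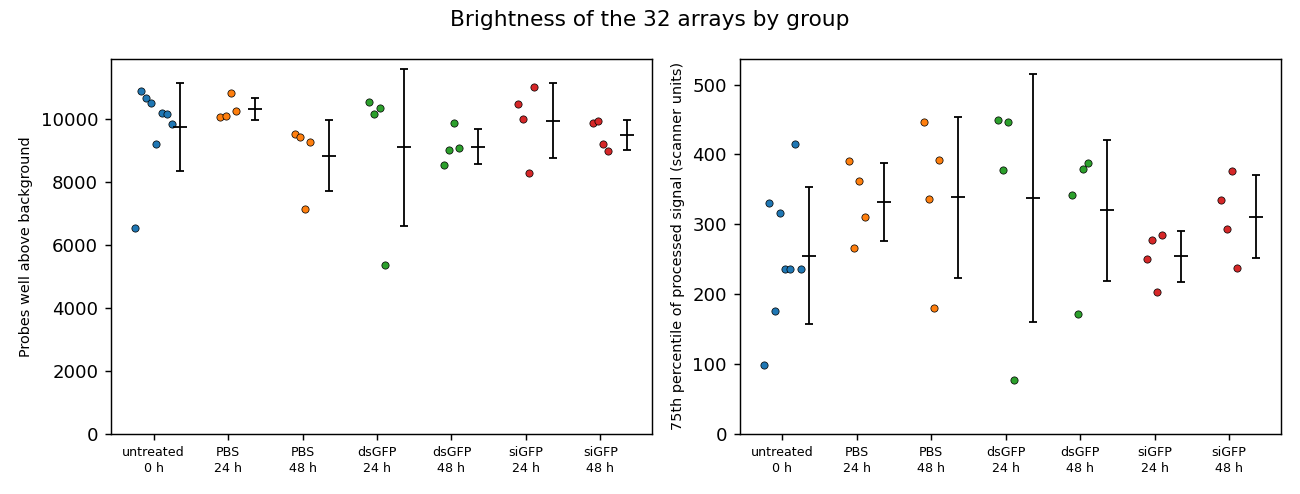
Probes well above background (left) and the 75th percentile of the processed signal in scanner units (right) for each array, by group. Points are arrays, bars the group mean and SD. The lowest point in each panel is dsGFP 24 h replicate 4, at 5369 probes and 76.4 units.

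The first question was what long double-stranded RNA without a shrimp target changed within 24 h. JN100568.1 was 13.9-fold higher in dsGFP than in PBS shrimp, at 4.98 ± 1.17 against 1.18 ± 0.97 log2 units relative to the array's 75th percentile (SD, n = 4 each; limma adjusted p = 0.000166). AB596876.1 was lower, at 1.77 ± 0.16 against 3.30 ± 0.14 (log2 fold change -1.53, SE 0.26, limma adjusted p = 0.000427). The probe wsv122 was 7.23-fold higher (adjusted p = 0.0392) and AB121741.1 lower (log2 fold change -2.64, adjusted p = 0.0419). Without the weak array of this group these 2 no longer passed (2.11, adjusted p = 0.165, and -1.55, adjusted p = 0.171), nor did they without PBS 24 h replicate 1 (2.96, adjusted p = 0.0799, and -2.71, 0.086), replicate 2 (2.85, 0.0903, and -2.42, 0.125) or replicate 4 (2.41, 0.18, and -2.49, 0.141), nor wsv122 without dsGFP 24 h replicate 2 (2.99, 0.0509). With untreated shrimp in place of PBS, wsv122 changed sign to -0.09. In all, 208 probes were higher and 69 lower of 11385 tested. Of these, 202 and 67 were assembled transcripts, 4 and 2 GenBank entries, and 2 and 0 wsv probes. Of the 277 calls 54 were also called for PBS at 24 h against untreated, a contrast that shares the PBS arrays, 0 of them in the same direction. The 208 higher probes had a median log2 fold change of -0.90 there. Without dsGFP 24 h replicate 4 alone the counts were 162 and 123. Without both weak arrays the counts were 219 and 203, with 223 of the 277 calls shared. In a model of these 2 groups alone they were 41 and 3. The count fell to 157 without PBS 24 h replicate 1 and to 177 without PBS 24 h replicate 4. Treatment and slide cannot be told apart here.

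At 48 h the same contrast asked whether the difference lasted. JN100568.1 was again higher after dsGFP, 14.8-fold (4.91 ± 0.15 against 1.02 ± 0.61, SD, n = 4 each; limma adjusted p = 0.000139), and AB520827.1 was 8.41-fold higher (4.10 ± 0.97 against 1.02 ± 0.55, adjusted p = 0.00627). AB121743.1 was lower, at 7.42 ± 0.91 against 10.22 ± 0.47 (log2 fold change -2.81, SE 0.66, limma adjusted p = 0.0112), and without dsGFP 48 h replicate 4 it no longer passed (-2.46, adjusted p = 0.052). The probe wsv329 was well above background on 4 of 4 PBS arrays and on 0 of 4 dsGFP arrays, at least 2.35-fold lower after dsGFP (limma adjusted p = 0.00503). With untreated shrimp in place of PBS it no longer passed (limma adjusted p = 0.255), and no fold is given, since no dsGFP array was well above background. In all, 281 probes were higher and 256 lower, among them 277 and 243 assembled transcripts, 4 and 9 GenBank entries, and 0 and 4 wsv probes. Median scaling gave 316 and 161. Without the weak arrays, which are not in this contrast but enter the shared variance, the counts were 704 and 883, and all 537 calls were among them. The count fell to 326 without PBS 48 h replicate 3 and to 295 without dsGFP 48 h replicate 1.

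Calls at both times numbered 103 higher and 17 lower, where independent lists would share 5.13 and 1.55. The 2 contrasts share no array but share slides. The GenBank entries called at both times were JN100568.1, AY545075.1 (2.15 and 2.34 log2 units higher), AB121741.1 and AB596876.1, named after their values were seen. Fold changes at the 2 times correlated across probes, which are not independent replicates, with r = 0.36 and covariance 0.28. Draws of unchanged groups gave r from -0.47 to 0.49 and covariances from -0.20 to 0.23 in 95% of 200 draws, so that r lay within and the covariance above the range. Without the weak arrays r was 0.54, against -0.28 to 0.32. The direct test of the difference between times, the dsGFP by time interaction, called 0 probes in limma, with 1296 at an unadjusted p under 0.05. The smallest limma adjusted p there was 0.281. Among probes without a locus number and well above background on every array of at least 1 group, the smallest p-values belonged to AB538455.1 (log2 difference 3.49, and 1.70 without the weak array dsGFP 24 h replicate 4) and AB520827.1 (2.51) on the positive side, and to AB505891.1 (-1.59) and wsv024 (-2.31) on the negative side, with limma adjusted p from 0.309 to 0.339.

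**Figure D2:**
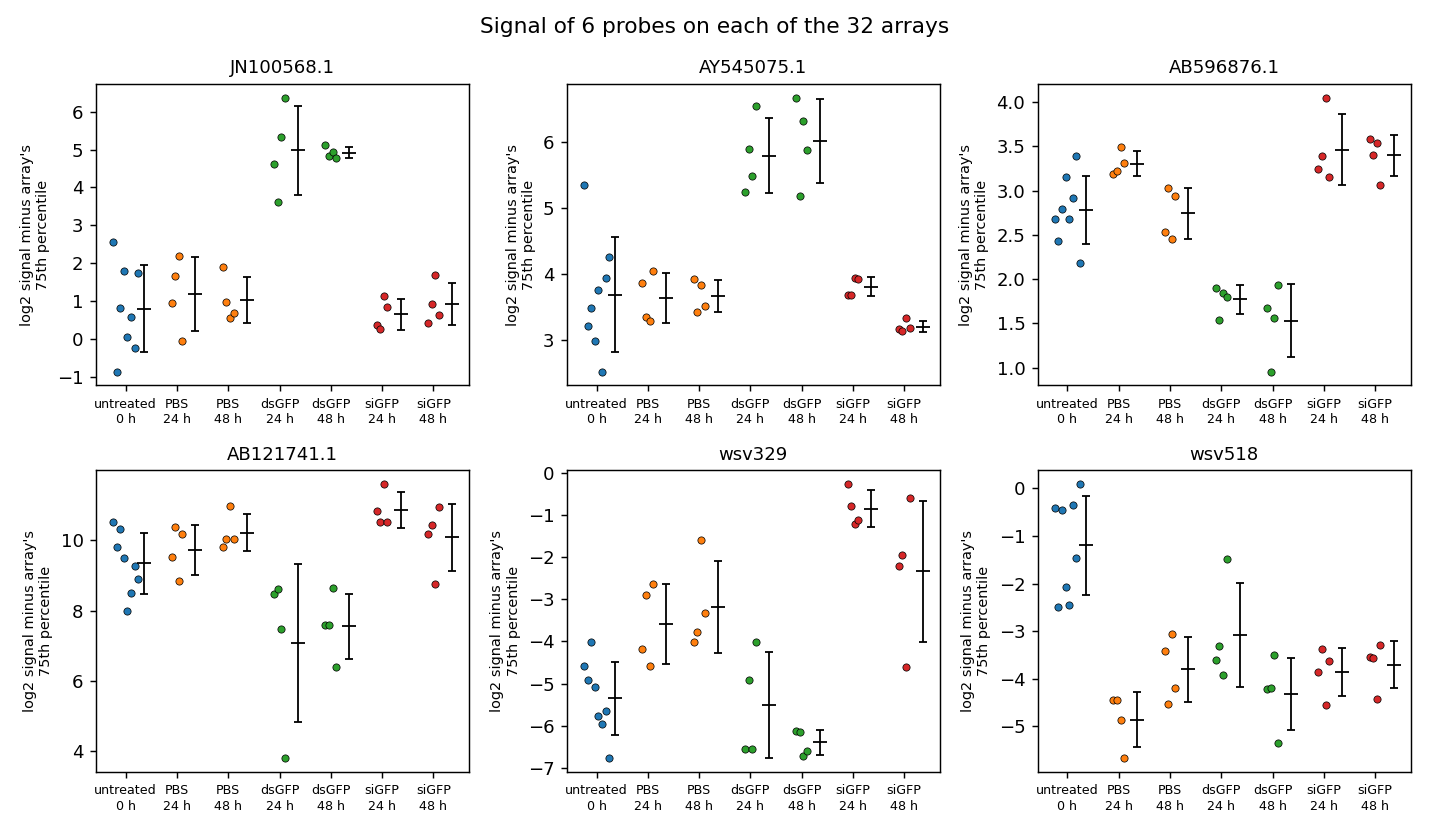
Log2 processed signal minus the array's 75th percentile for 6 probes, by group. Points are arrays, bars the group mean and SD. JN100568.1 lies at 4.98 and 4.91 on average after dsGFP and at 1.18 and 1.02 after PBS.

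For siGFP the contrast with PBS asked the same of short RNA. At 24 h 3 probes were higher and 0 lower, all assembled transcripts, with 732 at an unadjusted p under 0.05. Locus_5882 CUST_11095 was 20.3-fold higher (4.19 ± 0.43 against -0.15 ± 1.02, SD, n = 4 each; limma adjusted p = 0.0224) and Locus_3 CUST_9202 3.94-fold higher (adjusted p = 0.0381). With untreated shrimp in place of PBS the latter no longer passed (log2 fold change 0.06, adjusted p = 0.978). None passed without PBS 24 h replicate 1 or 4 or without siGFP 24 h replicate 2, 3 or 4, and 8 passed without PBS 24 h replicate 3. Locus_5882 CUST_11095 also missed the threshold without that array (log2 fold change 3.95, adjusted p = 0.0561), and Locus_3 CUST_9202 without PBS 24 h replicate 2 (1.94, adjusted p = 0.113) or siGFP 24 h replicate 1 (1.95, adjusted p = 0.149). At 48 h 7 probes were higher and 0 lower, with 470 at an unadjusted p under 0.05. Locus_20008 CUST_2436 and Locus_3 CUST_7684 were well above background on 4 of 4 siGFP arrays and 0 of 4 PBS arrays, at least 6.71-fold and 3.41-fold higher (limma adjusted p = 0.00382 and 0.0163). With untreated shrimp in place of PBS the latter no longer passed (log2 fold change 2.08, adjusted p = 0.0778). Without siGFP 48 h replicate 3 Locus_20008 CUST_2436 was at least 3.8-fold higher (adjusted p = 0.0491). Locus_3 CUST_7684 no longer passed without PBS 48 h replicate 1 or 2 (at least 2.99-fold and 3.11-fold, adjusted p = 0.102 and 0.0938) or siGFP 48 h replicate 3 or 4 (at least 3.26-fold and 2.96-fold, adjusted p = 0.075 and 0.0935). That count was 3 without PBS 48 h replicate 1 or siGFP 48 h replicate 3, and 4 without PBS 48 h replicate 2 or 4 or siGFP 48 h replicate 2. Without the weak arrays siGFP gave 73 higher and 5 lower at 24 h and 39 and 2 at 48 h. The siGFP by time interaction called 0 probes, with 290 at an unadjusted p under 0.05. Among probes without a locus number and well above background on every array of at least 1 group, the smallest p-values each way were those of AY769095.1 (log2 difference 2.36), AB247563.1 (0.93), wsv497 (-2.25) and the clone c62_A01D07_NP_477969 (-1.95), all with limma adjusted p of 1.00.

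Set directly against siGFP, dsGFP arrays again had higher JN100568.1, at 4.98 ± 1.17 against 0.66 ± 0.41 at 24 h and 4.91 ± 0.15 against 0.91 ± 0.55 at 48 h (SD, n = 4 each; limma adjusted p = 6.66e-05 and 5.21e-05), and higher AY545075.1, by 1.98 and 2.81 log2 units (adjusted p = 0.00382 and 4.70e-05). The probe wsv329 was lower at 24 h (-5.51 ± 1.26 against -0.84 ± 0.43, SD, n = 4 each; limma adjusted p = 0.000117), being well above background on 1 of 4 dsGFP arrays. AB121740.1 was lower at 24 h (log2 fold change -5.57, adjusted p = 0.0187), but was well above background on 3 of 4 dsGFP arrays. The weak array lay at -3.03 and the next at 7.28, so differences that take it in do not measure the fold. Without the weak array the log2 fold change was -2.81 (adjusted p = 0.00249). With that array kept it was -6.58, -6.63 and -6.25 without dsGFP 24 h replicate 1, 2 and 3. AB121740.1 no longer passed without siGFP 24 h replicate 1 (-5.54, adjusted p = 0.0507) or 3 (-5.35, adjusted p = 0.0579). At 48 h AB121742.1 and AB121743.1 were lower (log2 fold changes -2.55 and -2.54, adjusted p = 0.00326 and 0.021). AB121740.1 to AB121743.1 are consecutive entries. The means of AB121742.1 and AB121743.1 were alike (7.36 and 7.42 after dsGFP, 9.92 and 9.96 after siGFP), so they may not be independent results. AB121743.1 no longer passed without dsGFP 48 h replicate 1 or 4 (-2.52 and -2.20, adjusted p = 0.0586 and 0.0936) or siGFP 48 h replicate 1, 2 or 4 (-2.48, -2.40 and -2.29, adjusted p = 0.0597, 0.0697 and 0.0891). In all, 220 probes were higher and 236 lower at 24 h, and 259 and 264 at 48 h. The balance moved with the scaling: median scaling gave 411 and 120 at 24 h and 277 and 122 at 48 h, where the median log2 fold change of all probes was -0.17 in the main setting. Without the weak arrays the counts were 345 and 702, and 509 and 843. In a model of the 2 groups alone 45 probes passed at 24 h. The 24 h count was 717 without dsGFP 24 h replicate 1, 787 without dsGFP 24 h replicate 2, 244 without siGFP 24 h replicate 1 and 233 without siGFP 24 h replicate 3. The 48 h count was 291 without dsGFP 48 h replicate 1, 344 without dsGFP 48 h replicate 4, 340 without siGFP 48 h replicate 1 and 311 without siGFP 48 h replicate 4.

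Across probes, dsGFP and siGFP fold changes against the same PBS arrays correlated with r = 0.39 at 24 h and 0.32 at 48 h. Without the weak array dsGFP 24 h replicate 4 the former was 0.165, and without siGFP 48 h replicate 3 the latter was 0.204. Unchanged groups against shared controls gave a mean r of 0.49, from 0.02 to 0.88 in 95% of 200 draws. The covariances were 0.22 and 0.14, against 0.20 in those draws. With the PBS arrays split 2 and 2, r averaged 0.18 at 24 h and 0.02 at 48 h over 6 splits. In contrasts that share no array but share the PBS slide, the 208 probes higher after dsGFP at 24 h had a median log2 fold change of -0.11 for siGFP at 48 h (limma's fry, adjusted p = 0.704 over 8 tests), with 92 of 208 above 0. The 281 probes higher after dsGFP at 48 h had a median of 0.09 for siGFP at 24 h (limma's fry, adjusted p = 0.582), with 164 of 281 above 0. The lower lists did not follow dsGFP: the 69 probes lower at 24 h had a median of 0.16 for siGFP at 48 h, 23 of them with the same sign (limma's fry, adjusted p = 0.384), and the 256 lower at 48 h a median of 0.24 for siGFP at 24 h, 64 with the same sign (limma's fry, adjusted p = 0.310; limma's camera, adjusted p = 0.00727 at a preset correlation of 0.01 and 0.599 with an estimated correlation). For dsGFP at the other time, in contrasts sharing both slides, the same lists did follow: 197 of 208 and 257 of 281 of the higher probes and 63 of 69 and 195 of 256 of the lower had the same sign (limma's fry, adjusted p = 4.09e-05, 1.51e-07, 1.88e-05 and 0.0179). For the 256 lower at 48 h limma's camera gave adjusted p = 0.0994 with an estimated correlation.

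PBS shrimp were set against untreated shrimp for the effect of injection and time. At 24 h AB121209.1 was at least 9.69-fold higher, being well above background on 4 of 4 PBS and 0 of 8 untreated arrays (limma adjusted p = 0.0285), and AB121210.1 was higher (-1.14 ± 2.25, SD, n = 4, against -5.45 ± 0.87, SD, n = 8; limma adjusted p = 0.0462), well above background on 1 of 8 untreated arrays, so that no fold is given. The 2 entries are consecutive and alike after PBS (means of -1.17 and -1.14), so they may not be independent results. AB121209.1 was at least 17.3-fold higher without PBS 24 h replicate 1, and no longer passed without PBS 24 h replicate 2 (at least 5.11-fold, adjusted p = 0.132), 3 (at least 7.82-fold, adjusted p = 0.0932) or 4 (at least 12.7-fold, adjusted p = 0.0625) or untreated replicate 8 (at least 9.54-fold, adjusted p = 0.0533). AB121210.1 no longer passed without PBS 24 h replicate 2, 3 or 4 (adjusted p = 0.184, 0.133 and 0.0861) or without any 1 of the 8 untreated arrays (adjusted p from 0.0501 to 0.0729). The probe wsv518 was lower after PBS, at -4.87 ± 0.58 (SD, n = 4) against -1.20 ± 1.04 (SD, n = 8; limma adjusted p = 5.23e-05), and wsv078 at least 5.60-fold lower (adjusted p = 5.23e-05), being well above background on 0 of 4 PBS arrays. In all, 25 probes were higher and 343 lower, 15 of the lower ones wsv probes. Quantile normalization gave 58 and 274, and without the weak arrays there were 277 and 600. The count was 182 without PBS 24 h replicate 1 and 142 without PBS 24 h replicate 4.

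At 48 h wsv518 was again lower after PBS (-3.80 ± 0.68, n = 4; limma adjusted p = 0.00715), well above background on 1 of 4 PBS arrays, so that no fold is given. The probe wsv136 was at least 1.29-fold lower (adjusted p = 0.017). Locus_3 CUST_8314 and Locus_798 CUST_12134 were 5.53-fold and 4.92-fold higher (adjusted p = 0.0237 and 0.0295). The former no longer passed without any 1 of the 4 PBS 48 h arrays (log2 fold change 2.32 to 2.58, adjusted p from 0.053 to 0.105). The latter no longer passed without PBS 48 h replicate 1, 2 or 4 (2.44, 2.14 and 2.02, adjusted p = 0.0732, 0.126 and 0.15) or untreated replicate 1 or 8 (2.19 and 2.07, adjusted p = 0.0536 and 0.0641). Nor did wsv518 pass without PBS 48 h replicate 2 (adjusted p = 0.0671), or wsv136 without PBS 48 h replicate 1, 2 or 4 (adjusted p = 0.0808, 0.0913 and 0.0904). In all, 9 probes were higher and 119 lower. Quantile normalization gave 40 and 122, and without the weak arrays there were 72 and 269. With the array row as a covariate 9 probes passed. The count was 24 without PBS 48 h replicate 1 or 4, 19 without PBS 48 h replicate 2, 66 without untreated replicate 3 and 75 without untreated replicate 8. Both PBS times share the untreated arrays and had 102 lower calls in common, where independent lists would share 3.59. With the untreated arrays split by slide row, which is the same fit as the row covariate, 266 probes were lower at 24 h and 9 at 48 h. Of these 9 were shared, where independent lists would share 0.21. In that fit the row effect comes from the untreated arrays alone, weak replicate 1 among them.

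Between 24 h and 48 h on the same slide, 0 probes passed after PBS (limma, 506 at an unadjusted p under 0.05) and 0 after siGFP (381). The smallest limma adjusted p was 0.547 after PBS and 0.157 after siGFP. Among probes without a locus number and well above background on every array of at least 1 group, the smallest p-values after PBS were those of c62_A01D07_NP_477969 (log2 fold change 1.55) and wsv497 (1.37) among probes higher at 48 h, and of AB520827.1 (-1.91) and AB596876.1 (-0.56) among those lower, with limma adjusted p from 0.901 to 1.00. Among the same kind of probes after siGFP they were, each way, those of AB516427.1 (1.72), AB596879.1 (1.67), wsv127 (-1.21) and wsv240 (means of -4.31 at 48 h and -3.30 at 24 h), with limma adjusted p of 1.00. Without PBS 24 h replicate 4, 1 probe passed after PBS, and without siGFP 24 h replicate 1, 1 passed after siGFP. After dsGFP 4 probes were lower at 48 h, with 2055 at an unadjusted p under 0.05. Locus_3 CUST_8271 was lower (1.85 ± 0.95 at 24 h, -1.26 ± 1.03 at 48 h, SD, n = 4 each; limma adjusted p = 0.00518), though without dsGFP 48 h replicate 1 it no longer passed (log2 fold change -2.82, adjusted p = 0.0502). Locus_6285 CUST_11344 was lower too (-1.61 ± 0.53 at 24 h, -4.37 ± 1.19 at 48 h, SD, n = 4 each; limma adjusted p = 0.0492), well above background on 2 of 4 arrays at 48 h, so that no fold is given. It no longer passed without the weak array (adjusted p = 0.116), where the difference of measured means was -2.65 against -2.76, nor without dsGFP 24 h replicate 2 (adjusted p = 0.0688) or dsGFP 48 h replicate 1 or 4 (adjusted p = 0.236 and 0.197). With the array row as a covariate, its effect taken from the untreated arrays alone, 0 passed. The count was 13 without dsGFP 24 h replicate 2, 23 without dsGFP 24 h replicate 3, 1 without dsGFP 48 h replicate 1 and 18 without dsGFP 48 h replicate 3.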

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

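The tests of the dsGFP and of the PBS pattern, and the splits of the 2 interactions and of the calls shared between times, were chosen after the results were seen. Those on untreated replicate 2 were chosen after its pattern was seen, with their bounds set before they were run, except that the bound against a blemish was made stricter after its value was seen. An outlying array was found 14 times in 128 groups of values, where chance gives about 1 in 20. That rate does not hold for the counts of bright probes, where any count stands out once the other arrays have 0. The number of probes well above background was far below the rest of its group on PBS 48 h replicate 3 (7131, next 9270), dsGFP 24 h replicate 4 (5369, next 10145) and untreated replicate 1 (6538, next 9190). On dsGFP 24 h replicate 4 the 10 spike-in probes, RNA added in fixed amounts, averaged 7.91 log2 units (next 10.3), and 34 wsv probes were well above background (next 88). That array also stood apart for wsv122 (0.63, next -2.02), AB121740.1 (-3.03, next 7.28) and AB538455.1 (-4.01, next 2.53), in log2 units relative to the array's 75th percentile. PBS 48 h replicate 3 stood apart for wsv136 (-4.82, next -6.57), and siGFP 24 h replicate 4 for AB247563.1 (2.33, next 3.27). Probes over 16-fold brighter on 1 array than on any other numbered 108 on untreated replicate 2 (next 4 in its group), 8 on dsGFP 24 h replicate 4, 3 on siGFP 48 h replicate 4 and 1 on PBS 24 h replicate 3, the other arrays of those 3 groups having 0.

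For dsGFP against PBS, 1 of the 35 splits of the 8 arrays gave as many probes as the real one at each time, the real one itself. It gave 277 probes at 24 h (highest other 42) and 537 at 48 h (highest other 125). This argues against a chance division of the arrays, 1 of 35 being the smallest share these splits can give. The difference at 24 h does not rest on the weak array alone, since 422 probes passed without the 2 weak arrays and 285 without this array alone. Of the 277 calls 223 were kept without the 2 weak arrays. The balance moved from 208 higher and 69 lower to 162 and 123 without this array alone. The weak arrays enter the shared variance of every contrast. At 48 h, where neither takes part, the count rose from 537 to 1587 without them. The counts therefore do not show how much the weak array adds at 24 h. A shift of the dsGFP slide and a response to long RNA both predict fold changes alike at the 2 times. The correlation was 0.363, below the highest of the draws of unchanged groups (0.545), the bound set for it. Without the weak arrays the correlation was 0.545, above a highest draw of 0.479. Slide and treatment cannot be told apart, since slide 2 held dsGFP alone.

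Most probes that differed between PBS and untreated shrimp were lower after PBS. Dim signal does not account for this, since 91.4% of the 302 calls at 24 h were lower after PBS among probes well above background on all 12 arrays. A shift of a slide stays open for the 368 calls, since each group had a slide of its own, and so do injection and time. Only the real split of 100 drawn gave as many probes, 1 at 24 h (368, highest other 18) and 1 at 48 h (128, highest other 19). This argues against a chance division of the arrays, 1 of 100 being the smallest share these draws can give.

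The 108 probes bright on untreated replicate 2 alone had a median excess of 5.45 log2 units over the next array, and 48 of them came from Locus_3, 21 were GenBank entries and 0 wsv probes. These GenBank entries included the unbroken run of numbers from GQ354209.1 to GQ354220.1, and both EF375711.1 and EF375712.1. A blemish would raise such a run together only if its probes lay close on the array, which was not examined for them. A local blemish would place them side by side: the median distance to the nearest of them was 5.10 spots, at or above 13.2% of 1000 random sets. By the bound set in advance, any value within the middle 90% of the random sets (5 to 6.56 spots) or above would argue against a blemish, and this value met it. That bound was too lax, since the value lies close to the lower end of the spread, so after it was seen the median of the random sets (5.92) was used instead, and a blemish is not excluded. RNA of another source would raise other probes of the same loci, and 21.7% of the 23 such probes lay over 1 log2 unit above every other array, between the bounds set in advance for and against it. Over all probes of that array the share was 1.49%, while the median of the 23 lay 1.30 log2 units below the highest other array. Both explanations stay open, and no cell type could be tested without gene names. Leaving this array out gave 273, 526, 3 and 7 calls in the 4 comparisons of dsGFP or siGFP with PBS. This array enters those only through the shared variance, so they say little about its effect. PBS against untreated uses this array. Its count ranged from 142 to 421 at 24 h and from 19 to 171 at 48 h with each array left out in turn.

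The remaining splits were as follows. For siGFP against PBS 1 of 35 splits, the real one, gave as many probes at 24 h (3, highest other 1) and at 48 h (7, highest other 0). The same held for dsGFP against siGFP at 48 h (1 of 35, 523, highest other 3). This argues against a chance division of the arrays, 1 of 35 being the smallest share these splits can give. The few siGFP calls were fragile, with 0 at 24 h without PBS 24 h replicate 1. At 48 h they were 0 in a model of the 2 groups alone. For dsGFP against siGFP at 24 h 2 of 35 splits gave as many probes (456, highest other 547, with the weak array and siGFP 24 h replicate 2 exchanged). The count alone does not argue against chance there. Of the 456 calls 161 were also called at 48 h, all in the same direction, on other arrays of the same slides. Among the 35 splits of the 24 h arrays 1, the real one, shared as many (highest other 58). This argues against chance for the shared calls, again at the smallest share possible. For 48 h against 24 h after dsGFP chance could not be excluded (3 of 35, 4, highest other 21). Where 0 probes were called every split gives as many, so the splits decide nothing after PBS or siGFP (35 of 35, highest other 0 and 1) or for the interactions (100 of 100, highest other 2 for dsGFP and 7 for siGFP).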

How the results depend on the processing

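Fits without the 2 weak arrays or without untreated replicate 2 were chosen after seeing the data. Signal over background limits the dim probes. The cause of each change below was not tested unless stated.

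By normexp, siGFP against PBS at 48 h had 1 call, dsGFP against siGFP at 24 h 211, and PBS against untreated 236 at 24 h and 83 at 48 h. With median scaling siGFP against PBS at 48 h had 4, and PBS against untreated 226 and 64. In the deposited value table siGFP against PBS had 0 at 24 h and 3 at 48 h, and PBS against untreated 134 and 14. With only the groups compared, dsGFP against PBS at 24 h had 44, siGFP against PBS at 48 h 0, dsGFP against siGFP at 24 h 45, PBS against untreated at 48 h 50, and 48 h against 24 h had 0 after dsGFP and 1 after siGFP. Among probes well above background on all arrays compared, where fewer probes were tested, dsGFP against PBS at 48 h had 336, siGFP against PBS at 48 h 1, and PBS against untreated at 48 h 70. With the array row as a covariate PBS against untreated at 48 h had 9 and 48 h against 24 h after dsGFP 0. Against untreated shrimp in place of PBS, dsGFP had 719 calls at 24 h and 1326 at 48 h and siGFP 94 and 84, a contrast of 4 with 8 arrays, and wsv122 changed sign (log2 fold change -0.0886).

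The replicate number as a block gave 179 calls for dsGFP against PBS at 24 h, 287 for dsGFP against siGFP at 24 h, 169 and 10 for PBS against untreated at 24 h and 48 h, and 1 for 48 h against 24 h after siGFP, and moved no other count by over 1.5 times. Arrays sharing a number shared little else: deviations from the group means correlated from -0.32 to 0.31 over 60 pairs with the same number (median 0.01), and 9 of 24 arrays correlated best with an array of their own number.

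Without the 2 weak arrays dsGFP against PBS had 422 calls at 24 h and 1587 at 48 h, siGFP against PBS 78 and 41, dsGFP against siGFP 1047 and 1352, PBS against untreated 877 and 341, and 48 h against 24 h after dsGFP 8. Without untreated replicate 2, 48 h against 24 h after siGFP had 1.

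With each array left out in turn, dsGFP against PBS ranged from 157 to 408 at 24 h and from 295 to 601 at 48 h, siGFP against PBS from 0 to 8 and from 3 to 6, dsGFP against siGFP from 233 to 787 and from 291 to 515, and PBS against untreated from 142 to 421 and from 19 to 171. The time contrasts ranged from 0 to 1 after PBS, 1 to 23 after dsGFP and 0 to 1 after siGFP, and both interactions stayed at 0. The correlation of dsGFP and siGFP fold changes ranged from 0.165, without dsGFP 24 h replicate 4, to 0.455 at 24 h and from 0.204, without siGFP 48 h replicate 3, to 0.410 at 48 h, and at 24 h was 0.306 among probes well above background on all arrays compared.

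Quantile normalization, no filter on dim probes, the 2-fold minimum, and variances without trend and robust fitting kept the total count of each comparison within 1.5 times, but not each direction: for PBS against untreated the higher calls, 25 at 24 h and 9 at 48 h, were 58 and 40 with quantile normalization, and 14 at 24 h with no filter on dim probes, and for dsGFP against siGFP at 48 h the 264 lower calls were 166 with quantile normalization. The list tests gave no value under any setting, since no list had members. Of 46 named values 30 passed in the main setting. Of these 30, 12 no longer passed with normexp, 9 in the deposited table, 10 with the block and 15 with only the groups compared. With the array row as a covariate 7 of 10 no longer passed. Against untreated shrimp in place of PBS 3 of 12 no longer passed and 1 changed sign. With one array left out 67 of 272 values that had passed did not.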

Other observations

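The wsv probes, of which the array holds 526, were well above background on 34 to 147 per array, with group medians of 92 in untreated shrimp, 99 and 65.5 after PBS, 89 and 58 after dsGFP, and 105.5 and 80 after siGFP, at 24 h and 48 h. Over all probes these medians fell too, from 10177.5 to 9339 after PBS, 10235 to 9039.5 after dsGFP and 10237.5 to 9527.5 after siGFP. The 24 h arrays lay in row 1 and the 48 h arrays in row 2. Untreated arrays, without a time difference, showed a like pattern. Apart from weak replicate 1 (6538, wsv 46), row 1 had 10490 to 10878 probes well above background and 108 to 128 wsv probes. Row 2 had 9190 to 10169 and 78 to 94. Row and time cannot be told apart in these falls. The median log2 fold change of the wsv probes at 48 h against 24 h was 0.11 after PBS, -0.51 after dsGFP and -0.38 after siGFP. Of the 138 wsv probes tested, 0 were called at 24 h and 48 h for siGFP against PBS. With p adjusted over this class alone, 5 were higher at 24 h, where the class had a median log2 fold change of 0.48, and 1 at 48 h (median 0.01). For dsGFP against PBS the class alone gave 0 calls at 24 h and 2 lower at 48 h, against 2 higher and 4 lower over all probes. For PBS against untreated it gave 1 higher and 21 lower at 24 h and 3 higher and 22 lower at 48 h, against 15 and 5 lower over all probes.

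Loci with several probes, Locus_3 left out, gave a check of the calls within a transcript assembly. For dsGFP against PBS, 7 of 7 loci with 2 or more calls went one way at 24 h and 13 of 14 at 48 h. Of the probes of called loci that were not called themselves, 65.3% of 49 at 24 h and 64.2% of 106 at 48 h had the sign of the called ones. Their median log2 fold change in the called direction was small, 0.22 and 0.36. All called probes had a median absolute log2 fold change of 2.12 and 1.82. For PBS at 24 h against untreated 3 of 4 loci went one way, and 56.8% of 81 probes had the sign of the called ones.

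Among the 108 probes bright on untreated replicate 2 alone, the GenBank entry EF375712.1 was the farthest from the other arrays, at 8.16 against at most -3.40 log2 units, followed among GenBank entries by AY887065.1 (4.59 against -4.01) and AB504528.1 (7.03 against -1.20). These were chosen after their values were seen. The value -4.01 was also the highest other one for further entries, GQ354211.1 and GQ379203.1 among them. It was the signal of AB538455.1 on the weak array dsGFP 24 h replicate 4 as well. Such a repeat points to the lowest signal of that array rather than a measured level, so distances from it are uncertain.

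Tests of whole probe classes, chosen after the files were examined, gave no shift of the 423 GenBank entries that held with an estimated correlation: for dsGFP against PBS at 24 h limma's camera gave adjusted p = 1.19e-08 at a preset correlation of 0.01 and adjusted p = 0.45 with an estimated correlation (median log2 fold change -0.33). Of the other classes, the 10812 assembled transcripts passed with an estimated correlation in 4 of the 8 comparisons tested. Relative to the other classes they were higher for dsGFP against PBS at 48 h (adjusted p = 0.0034, median log2 fold change -0.07, against -0.84 for GenBank entries) and siGFP against PBS at 48 h (adjusted p = 0.0376, median 0.04), and lower for PBS against untreated at 24 h (adjusted p = 0.0465, median -0.04) and 48 h (adjusted p = 0.0477, median -0.08). This class holds most of the 11385 tested probes, so these tests set it against the few others, and each comparison is between slides. The test allows for correlation inside the class tested, estimated at 0.04, but not among the others, 0.28 for GenBank entries. Tested from that side, GenBank entries did not pass for dsGFP against PBS at 48 h (limma's camera, adjusted p = 0.257 with an estimated correlation). The 4 passes therefore do not show a shift of the class.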
